A study of Mus musculus with 33 samples.

How the data were processed

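ChIP-seq reads of Gata4, Mef2c and Tbx5 and of input chromatin were compared in a mouse cardiac fibroblast line, in 33 libraries. Per the labels, the Gata4 and Tbx5 antibodies were goat antibodies of the same supplier, and the Mef2c antibody came from another supplier. The values analysed were whole-number read counts per region, deposited by the authors as a single table for all libraries with no normalisation. Per the submitters' processing notes, read quality was checked with FastQC, reads were aligned with Bowtie2 2.2.4 and counted with featureCounts, and the build was mm9. Aligner settings, duplicate handling and the way the regions were selected are not given in the sources used here. If the regions were selected on the same ChIP libraries, every count of enriched regions depends on that selection, and signal outside the regions was not analysed here. Regions reached beyond the mm9 length on 0 of 21 chromosomes and beyond that of mm10 on 9. They did not overlap, and 0 lines lacked a region. No gene was assigned to a region, because the gene table at hand describes another build (GRCm38.p6), and the gene list and motif tests written beforehand were not run.

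Groups were taken from the sample labels. Pairs of libraries within a group were compared with a chi-square test of their counts, and libraries that agree within sampling noise where other pairs of the group differ were summed and counted once (Gata4 with all 3 factors 1 and 6, inputs of the same cells 1 and 3, and inputs 2, 4 and 5). The tests, the groups in each and the rule for naming regions were fixed before the data were examined, as were most alternatives, whereas which libraries count as 1 sample was set from their counts. Those added later are named with their effects.

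Each comparison of groups used edgeR's quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest) on the counts as deposited, with TMM scaling and edgeR's filter on low counts (minimum count 10, minimum total 15). Adjusted p are Benjamini-Hochberg values over the regions tested, all tests were two-sided, and a region was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM are counts scaled to a common library total, taken over the regions, and log2 CPM used a prior count of 2. Each ChIP group was compared with all 6 inputs as a single arm, because each single-factor input is 1 library. The test of differences between context effects used 1 fit of all 6 ChIP groups. Overlaps, widths, chromosomes and region classes were tested with Fisher's exact test, which takes regions, not samples, as independent units. edgeR weighted the libraries by their depth over the regions (97474 to 2377616 counts). Counting intervals and floors (3 counts over a group) are at the 95% level and cover counting error only.

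Regions named in the text were those with an adjusted p under 0.05, a mean log2 CPM above the median of the tested regions and every sample of a group beyond every sample of the other. Of these, the 10 with the largest log2 fold change in each direction were taken, the first 3 with full values and the others as ranges. The ranges are of fitted log2 fold changes, which depend on the prior count where a group has few or no counts. Medians of called regions were the same at the printed precision with regions of no count in a group at their lower bound.

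Replicate numbers were tested for pairing by correlating the deviations of same-numbered samples from their group means. In cells with all 3 factors, Gata4 and Tbx5 samples of a number deviated together (r from 0.16 to 0.37 over 4 numbers), as did Mef2c and Tbx5 samples (0.2 to 0.54), so these numbers pair the samples. Other pairs of groups had a same-numbered pair at or below 0.1.

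Simulated counts from each comparison's means, totals and spread had 200 regions changed by known folds. Real comparisons called far more regions, so the shares below do not test the scaling and need not hold there. From alone to with the others, 10, 16 and 24% of 2-fold changes and 91, 95 and 87% of 4-fold changes were recovered for Gata4, Mef2c and Tbx5 (18998, 16188 and 17112 regions), with 8.18, 3.48 and 7.5% of calls false. For the factors alone, 5, 2 and 37% of 2-fold and 43, 35 and 97% of 4-fold changes were recovered for Gata4 against Mef2c, Gata4 against Tbx5 and Mef2c against Tbx5 (20737, 17092 and 17616 regions), with 5.88, 5.13 and 4.96% false. In cells with all 3 factors these shares were 11, 21 and 16% and 94, 99 and 94% (26521, 23911 and 22765 regions), with 5.41, 5.51 and 4.35% false. Against input, the shares alone were 10, 34 and 44% and 89, 93 and 100% for Gata4, Mef2c and Tbx5 (13695, 20034 and 10373 regions), with 3.88, 4.51 and 4% false. With the others they were 34, 13 and 30% and 97, 95 and 93% (24669, 22258 and 25852 regions), with 2.96, 3.57 and 1.6% false.

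Alternatives included DESeq2 size factors and Wald tests, scaling by library totals, no filter, 1 fit of all groups, a block on the replicate number, the matched input only, a log2 fold change over 1 as a further criterion, inputs split between factors and leaving out each sample. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.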

Results

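Occupancy of 3 transcription factors was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) during direct reprogramming of fibroblasts toward a cardiac fate. The factors were Gata4, a zinc-finger protein that binds GATA sequences, Mef2c, a MADS-box protein, and Tbx5, a T-box protein. The cells were a line of cardiac fibroblasts from newborn mice that had been immortalised with large T antigen and carried a green fluorescent reporter driven by an alpha myosin heavy chain promoter. They were infected either with retroviruses for all 3 factors or with the virus of a single factor, were kept with an inhibitor of TGF-beta signalling and an inhibitor of Wnt signalling, and were harvested without sorting at day 2. With all 3 factors there were 6 libraries for Gata4, 4 for Mef2c, 4 for Tbx5 and 6 of input chromatin. With a single factor there were 4 libraries for Gata4, 3 for Mef2c, 3 for Tbx5 and 1 input for each factor. The labels call the libraries of a group biological replicates. Below, "alone" stands for the cells with a single factor and "with the others" for the ChIP of that factor in cells with all 3 factors.

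The values were raw read counts in 30815 regions of 201 to 1484 bp (median 234 bp) on the mm9 build of the mouse genome. Library totals over these regions ran from 352015 to 941173 for Gata4 with the others, from 383071 to 2377616 for Mef2c and from 580261 to 1431928 for Tbx5. Alone, they ran from 222761 to 591033 for Gata4, from 918300 to 968131 for Mef2c and from 334761 to 485430 for Tbx5. The inputs were shallower, at 165517 to 301678 with all 3 factors and 127871, 125181 and 97474 for Gata4, Mef2c and Tbx5 alone. The libraries numbered 1 and 6 of Gata4 with the others agree within sampling noise (chi-square per degree of freedom 1.013, p = 0.0785, against 1.342 to 2.992 for the other pairs of this group). They were counted as 1 sample. Inputs 1 and 3 with all 3 factors also agree within sampling noise, as do inputs 2, 4 and 5, and each set was counted as 1 sample. The same chi-square test gave p = 0.467 for the former and p from 0.272 to 0.949 for the latter. This left 5 samples of Gata4 with the others and 6 inputs in all.

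The tenth of regions with the most counts held 32.6 ± 2.85% of the counts of Gata4 with the others (SD, n = 5), 41.4 ± 3.59% for Mef2c (n = 4) and 38.1 ± 1.02% for Tbx5 (n = 4), against 21.2 ± 0.789% in the inputs with all 3 factors (n = 3), where a sample of several libraries entered as the mean of their shares. Alone, this share was 55.4 ± 0.233% for Mef2c (n = 3) and 43.8 ± 1.34% for Tbx5 (n = 3). For Gata4 alone it was 33.3 ± 8.17% (n = 4), with a lowest sample at 21.2%. At the 500 regions most enriched for Gata4 with the others, 3 of the Gata4 alone libraries had log2 enrichments over the inputs with all 3 factors of 1.51, 1.69 and 1.63. The library labelled Gata4 alone number 4 had 0.13 there, within the range of the inputs (-0.11 to 0.16). It was kept in its group, and values without it are given beside the main comparisons that it moved most.

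**Figure D1:**
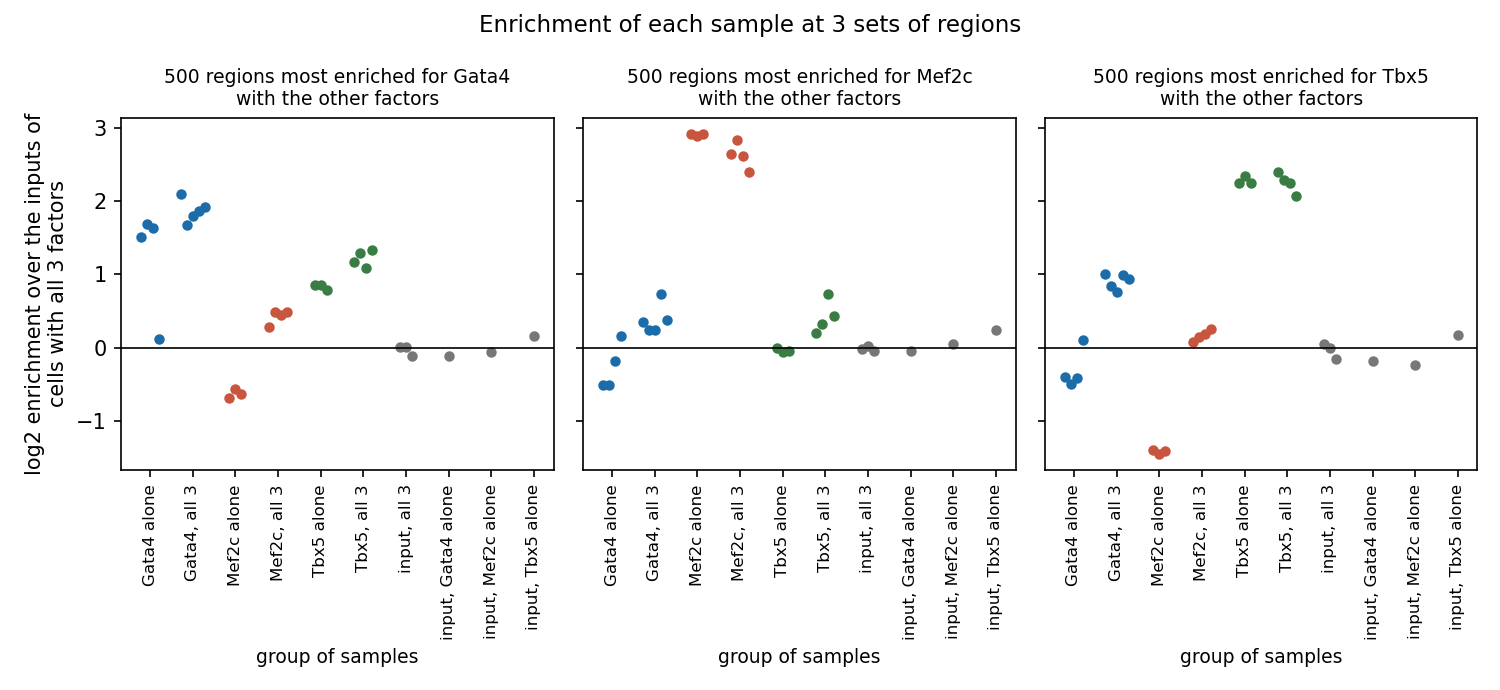
Points are samples, and the vertical axis gives the log2 share of counts at 500 regions over that share in the inputs with all 3 factors, for the regions most enriched for Gata4, Mef2c and Tbx5 with the others. The library labelled Gata4 alone number 4 sits at 0.13 in the Gata4 panel, and the other Gata4 alone samples sit between 1.51 and 1.69.

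The study's first question, from its title and labels, was how the binding of a factor differs when the other factors are present. Gata4 occupancy differed between the settings at 6589 of 20759 regions tested, of which 3427 were higher with the others and 3162 lower. Median log2 fold changes were 1.48 among the gains and -1.39 among the losses, and the change exceeded 2 on the log2 scale at 536 gained and 293 lost regions. Means below are CPM ± SD over 5 samples with the others and 4 alone. At chromosome 5, 35963704 to 35964007, the means were 156 ± 48.9 CPM with the others and 9.16 ± 6.49 alone, a log2 fold change of 4.18 ± 0.45 (SE, adjusted p = 3.81e-05). Chromosome 6, 58846640 to 58847068, had 101 ± 10.5 against 8.25 ± 4.66 CPM, a log2 fold change of 3.53 ± 0.39 (adjusted p = 3.81e-05). Next came chromosome 16, 24367243 to 24367686, with 180 ± 34.1 against 16.8 ± 11.2 CPM and a log2 fold change of 3.50 ± 0.41 (adjusted p = 5.22e-05). At chromosome 14, 57304271 to 57304499, the means were 9.42 ± 3.56 CPM with the others and 70.1 ± 31.7 alone, a log2 fold change of -2.96 ± 0.37 (SE, adjusted p = 6.9e-05). Chromosome 13, 34658503 to 34658877, had 13.2 ± 3.6 against 89.8 ± 23.6 CPM, a log2 fold change of -2.83 ± 0.31 (adjusted p = 3.81e-05). Next came chromosome 5, 105929237 to 105929534, with 10.2 ± 3.44 against 66.2 ± 24 CPM and a log2 fold change of -2.81 ± 0.35 (adjusted p = 6.9e-05). The next 7 gains ranged from 2.99 to 3.30 and the next 7 losses from -2.56 to -2.74, with adjusted p at most 0.000257 and 9.87e-05. Leaving out the library labelled Gata4 alone number 4 raised the count to 11045 regions (5943 higher and 5102 lower), and leaving out Gata4 alone number 1 or 2 gave 4109 or 3680. The libraries with all 3 factors fell into sets by their Y chromosome reads. With only Gata4 libraries 1, 3 and 6 the count was 2864 and with only 2, 4 and 5 it was 3848, or 8825 and 9357 without Gata4 alone number 4.

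Mef2c differed at the largest number of regions of the 3 factors, 11648 of 19391 tested. With the others it was higher at 6071 regions, with a median log2 fold change of 1.91, and lower at 5577, with a median of -1.38. Changes beyond 2 on the log2 scale numbered 2789 among the gains and 1117 among the losses. Values are mean CPM ± SD over 4 samples with the others and 3 alone, and where a group held 1 to 3 counts in all, the ratio of its count rate is given with its counting interval. At chromosome 13, 75939892 to 75940120, means were 76.6 ± 25.3 CPM with the others and 0.354 ± 0.613 alone, a count ratio of 207 (95% interval 37 to 8210, adjusted p = 8.05e-09). Chromosome 7, 24901858 to 24902058, had 56.3 ± 11.9 CPM with the others and 0.698 ± 0.605 alone, a count ratio of 75.8 (95% interval 20.8 to 629, adjusted p = 1.82e-08). At chromosome 7, 136955287 to 136955503, means were 72.3 ± 26.2 CPM with the others and 1.05 ± 1.06 alone, a count ratio of 66.1 (95% interval 22.5 to 322, adjusted p = 3.48e-08), and Mef2c number 4 lay far below its group with the others there. At chromosome 15, 24563996 to 24564198, the means were 6.44 ± 3.04 CPM with the others and 93.2 ± 11.3 alone, a log2 fold change of -4.26 ± 0.36 (SE, adjusted p = 3.01e-09). Chromosome 8, 45929595 to 45929879, had 12.2 ± 9.33 against 150 ± 56.8 CPM, a log2 fold change of -4.25 ± 0.38 (adjusted p = 4.39e-09). Next came chromosome 5, 10444312 to 10444677, with 19.8 ± 8.47 against 289 ± 71.1 CPM and a log2 fold change of -4.16 ± 0.32 (adjusted p = 9.25e-10). Log2 fold changes of the next 7 named higher regions ran from 5.12 to 5.47, and of the next 7 lower ones from -3.78 to -4.09, with adjusted p at most 2.99e-08 and 9.85e-08. The share of calls that were gains was 52.1%, but 64% when counts were scaled by library totals and 38.7% with no filter on low counts. Libraries 1, 3 and 6 include only 1 of Mef2c, and with 2, 4 and 5 the count was 10452.

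Tbx5 was higher with the others at 3087 of 16395 regions tested and lower at 2437. The medians were 1.63 and -1.22 on the log2 scale, and 844 gains and 352 losses went beyond 2. CPM are means ± SD over 4 samples with the others and 3 alone. At chromosome 7, 148318083 to 148318437, the means were 68.9 ± 35.8 CPM with the others and 2.94 ± 2.57 alone, a log2 fold change of 4.33 ± 0.73 (SE, adjusted p = 0.000673). Chromosome 12, 118766982 to 118767250, had 66 ± 22.6 against 3.14 ± 5.44 CPM, a log2 fold change of 4.25 ± 0.66 (adjusted p = 0.000389). Next came chromosome 7, 117805419 to 117805833, with 67.9 ± 9.07 against 3.43 ± 5.95 CPM and a log2 fold change of 3.99 ± 0.58 (adjusted p = 0.000259). At chromosome 2, 118197551 to 118197770, the means were 14.4 ± 5.77 CPM with the others and 200 ± 67.8 alone, a log2 fold change of -3.87 ± 0.33 (SE, adjusted p = 2.98e-05). Chromosome 13, 114017411 to 114017613, had 10.7 ± 6.44 against 129 ± 18.5 CPM, a log2 fold change of -3.71 ± 0.38 (adjusted p = 4.25e-05). Next came chromosome 5, 136712668 to 136712879, with 11.3 ± 5.67 against 133 ± 41.9 CPM and a log2 fold change of -3.56 ± 0.35 (adjusted p = 3.69e-05). The other 7 named higher regions lay between 3.49 and 3.87 on the log2 scale and the other 7 lower ones between -2.83 and -3.23, with adjusted p at most 0.000446 and 0.00451. Libraries 1, 3 and 6 include only 1 of Tbx5, and with 2, 4 and 5 the total was 4336, against 5524 with all. For every factor, cells with all 3 factors and with a single factor were separate libraries and inputs, in part with different Y chromosome reads. The other factors and a difference between cell populations thus cannot be told apart here.

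**Figure D2:**
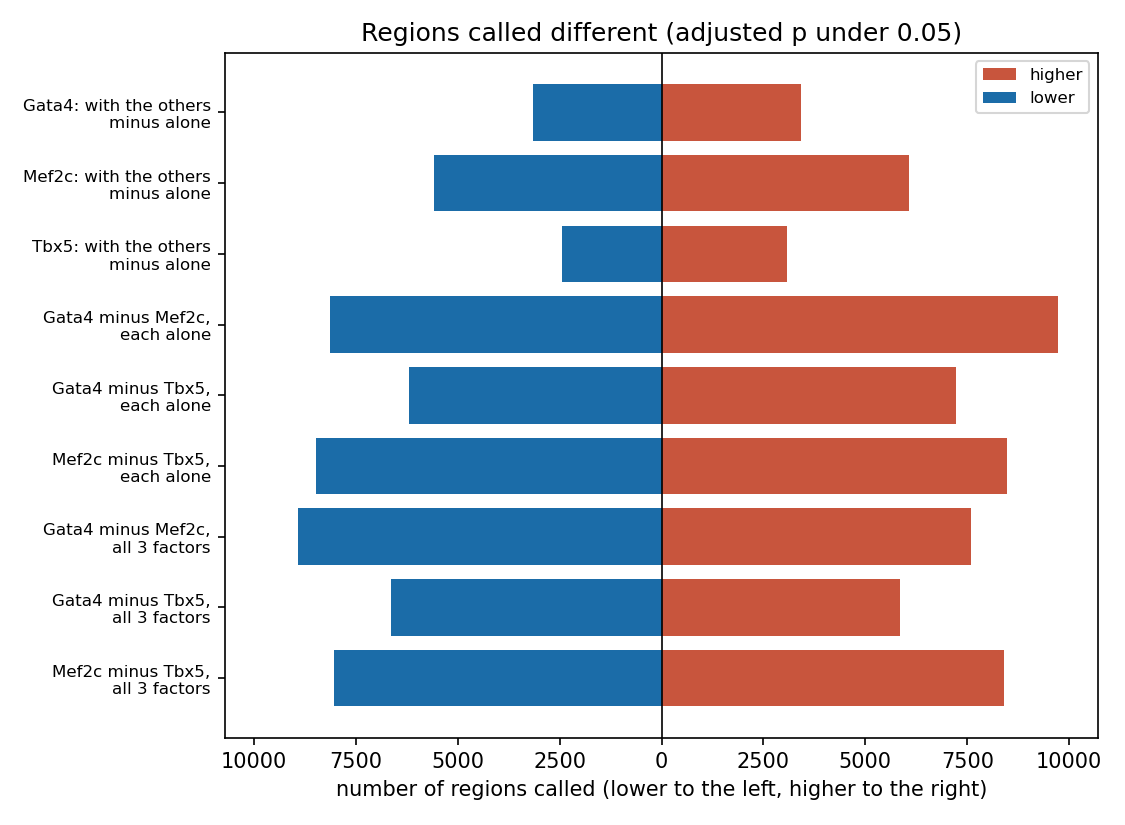
Bars give the number of regions called lower (left) and higher (right) at an adjusted p under 0.05 in each comparison between ChIP groups. Among the context comparisons Mef2c has the longest bars, with 6071 regions higher and 5577 lower.

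Gains of different factors fell on shared regions more often than independent lists would. Among regions tested for both, Gata4 and Mef2c shared 2350 gains against 1125 for independent lists (odds ratio 10.5), Gata4 and Tbx5 shared 1610 against 699.2 (6.7), and Mef2c and Tbx5 shared 2151 against 1138 (8.15). Fisher's exact test over regions, adjusted over all overlaps, gave 4e-300 for each. Of the losses, 316 were shared by Gata4 and Mef2c against 168 (odds ratio 2.51, adjusted p = 2.57e-33), 145 by Gata4 and Tbx5 against 66.95 (2.7, 3.43e-20) and 255 by Mef2c and Tbx5 against 185.3 (1.54, 2.3e-08). Opposite changes were rarer than for independent lists, as with 119 regions that gained Gata4 and lost Mef2c against 522.6 (odds ratio 0.154). Leaving out any 1 sample kept the side of the test of every overlap except that of Mef2c and Tbx5 losses, whose odds ratio was 1.11, 1.06 or 1.05 without Tbx5 alone number 1, 2 or 3 (exact p = 0.186, 0.472 and 0.558). Shared gains of Gata4 and Mef2c numbered 3592 against 1867 without Gata4 alone number 4, and 1337 to 1456 without number 1, 2 or 3, where those of Gata4 and Tbx5 were 902 to 994. The 119 opposite changes became 34 to 333. These comparisons shared no libraries, although they shared the cells with all 3 factors, and the overlap was tested after the counts had been seen.

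The change from alone to with the others also differed between factors when this difference was itself tested, over 30663 regions. It was higher for Gata4 than for Mef2c at 2792 regions and lower at 1350, higher for Gata4 than for Tbx5 at 811 and lower at 289, and higher for Mef2c than for Tbx5 at 1551 and lower at 2519. Scaling by library totals moved the share of these calls that were higher from 67.4% to 23.9% for Gata4 against Mef2c and from 38.1% to 76.4% for Mef2c against Tbx5. The total for Gata4 against Mef2c, 4142, became 6552 without the library labelled Gata4 alone number 4, 2567 without Gata4 alone number 1, and 2555 or 2606 without Mef2c alone number 1 or 3. The total for Gata4 against Tbx5, 1100, became 2966 without Gata4 alone number 4, and 494 to 699 without Gata4 alone number 1 or 2, Tbx5 alone number 1 or 2 or Tbx5 with the others number 2, 3 or 5. The total for Mef2c against Tbx5, 4070, was 2446 without Tbx5 alone number 1.

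Factors were next compared with one another in the cells that expressed each alone. Gata4 and Mef2c differed at most of the 21509 regions tested, with 9727 higher for Gata4 (median log2 fold change 2.40) and 8144 higher for Mef2c (median -2.92). Antibody and factor differ together in such comparisons. Mean CPM ± SD are over 4 Gata4 and 3 Mef2c samples. At chromosome 10, 40070059 to 40070314, the mean was 70.8 ± 32.2 CPM for Gata4 with a count of 0 for Mef2c, at least 74.8-fold higher (adjusted p = 1.42e-06). Chromosome 11, 104829799 to 104830074, had 201 ± 141 CPM for Gata4 and 0.707 ± 0.613 for Mef2c, a count ratio of 336 (95% interval 92.4 to 2780, adjusted p = 3.29e-06), and number 4 lay far below the other Gata4 samples there. At chromosome 3, 49964208 to 49964625, means were 84.7 ± 65.4 CPM for Gata4 and 0.354 ± 0.613 for Mef2c, a count ratio of 282 (95% interval 50 to 11200, adjusted p = 1.51e-05). At chromosome X, 46633201 to 46633403, the means were 4.19 ± 3.7 CPM for Gata4 and 241 ± 6.18 for Mef2c, a log2 fold change of -6.85 ± 0.48 (SE, adjusted p = 1.63e-09). Chromosome 13, 83600860 to 83601062, had 3.16 ± 1.49 against 191 ± 26.8 CPM, a log2 fold change of -6.76 ± 0.47 (adjusted p = 1.63e-09). Next came chromosome X, 38986010 to 38986343, with 6.35 ± 4.77 against 294 ± 21.9 CPM and a log2 fold change of -6.57 ± 0.41 (adjusted p = 1.54e-09), and number 4 lay far above the other Gata4 samples there. Ranks below held 7 more higher regions between 6.12 and 6.50 and 7 more lower ones between -6.17 and -6.45, with adjusted p at most 2.07e-05 and 9.65e-09. Regions higher for Gata4 made up 54.4% of the calls, and 65.9% with scaling by library totals.

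Gata4 alone and Tbx5 alone differed at 13397 of 18790 regions. Gata4 was higher at 7212 (median log2 fold change 2.26) and Tbx5 at 6185 (median -2.07). Means and SD of CPM are over 4 Gata4 and 3 Tbx5 samples. At chromosome 5, 5610421 to 5610643, means were 79.8 ± 39.7 CPM for Gata4 and 0.785 ± 1.36 for Tbx5, a count ratio of 112 (95% interval 19.9 to 4460, adjusted p = 1.96e-05), and number 4 lay far below the other Gata4 samples there. Chromosome 3, 69024560 to 69024785, had 84.3 ± 44.3 CPM for Gata4 and 1.57 ± 2.72 for Tbx5, a count ratio of 59.3 (95% interval 16.2 to 494, adjusted p = 3.95e-05), again with number 4 far below the other Gata4 samples. At chromosome 7, 130587459 to 130587665, means were 79.1 ± 45.7 CPM for Gata4 and 1.37 ± 2.38 for Tbx5, a count ratio of 56.1 (95% interval 15.3 to 468, adjusted p = 4.59e-05). At chromosome 13, 20641902 to 20642105, the means were 6.07 ± 8.1 CPM for Gata4 and 209 ± 14.4 for Tbx5, a log2 fold change of -5.64 ± 0.59 (SE, adjusted p = 5.25e-06). Chromosome 2, 18752751 to 18752960, had 8.43 ± 3.47 against 302 ± 79.9 CPM, a log2 fold change of -5.27 ± 0.45 (adjusted p = 2.81e-06). Next came chromosome 10, 80192221 to 80192473, with 7.05 ± 6.02 against 222 ± 56.1 CPM and a log2 fold change of -5.26 ± 0.55 (adjusted p = 5.25e-06). The other 7 named higher regions lay between 5.10 and 5.31 on the log2 scale and the other 7 lower ones between -5.06 and -5.24, with adjusted p at most 8.54e-05 and 7.52e-06.

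Of 18653 regions compared between Mef2c alone and Tbx5 alone, 8477 were higher for Mef2c (median log2 fold change 3.17) and 8479 for Tbx5 (median -2.48). This balance depended on the scaling, with 7428 and 9416 under library totals and 9386 and 7669 with DESeq2. Several of the strongest Mef2c regions held no Tbx5 count at all, and their folds are lower bounds against a floor of 3 counts over the Tbx5 group. Means are CPM ± SD over 3 samples of each. At chromosome 14, 34946927 to 34947136, the mean was 124 ± 14.4 CPM for Mef2c with a count of 0 for Tbx5, at least 51.5-fold higher (adjusted p = 4.09e-17). Chromosome 10, 41450846 to 41451069, had 96.7 ± 18.8 CPM for Mef2c and no count for Tbx5, at least 40.2-fold higher (adjusted p = 1.51e-15). Chromosome X, 147617346 to 147617548, had 75.9 ± 11.2 CPM for Mef2c and no count for Tbx5, at least 31.6-fold higher (adjusted p = 1.59e-14). At chromosome 2, 172234553 to 172234756, means were 0.354 ± 0.613 CPM for Mef2c and 122 ± 5.64 for Tbx5, a count ratio of 343 (95% interval 60.6 to 13600, adjusted p = 1.41e-15). Chromosome 4, 136358347 to 136358635, had 1.07 ± 1.06 CPM for Mef2c and 227 ± 17.4 for Tbx5, a count ratio of 214 (95% interval 72.6 to 1050, adjusted p = 1.31e-18). At chromosome 1, 192877549 to 192877802, means were 1.04 ± 1.03 CPM for Mef2c and 228 ± 69.4 for Tbx5, a count ratio of 207 (95% interval 70.2 to 1010, adjusted p = 5.44e-18). Log2 fold changes of the next 7 named higher regions ran from 7.64 to 8.81, and of the next 7 lower ones from -6.30 to -6.50, with adjusted p at most 2.67e-13 and 2.55e-14. Of the higher ones 1 had no Tbx5 count, so that its fitted value is no bound.

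In cells with all 3 factors, Gata4 and Mef2c differed at 16513 of 26167 regions, 7596 higher for Gata4 (median log2 fold change 1.57) and 8917 higher for Mef2c (median -2.15). A region on chromosome 11 that was among the strongest for Gata4 alone was again among the strongest here. Values are mean CPM ± SD over 5 Gata4 and 4 Mef2c samples. At chromosome 2, 170186394 to 170186763, the means were 80.5 ± 31.1 CPM for Gata4 and 0.945 ± 1.21 for Mef2c, a log2 fold change of 5.56 ± 0.54 (SE, adjusted p = 1.83e-09). Chromosome 11, 104829799 to 104830074, had 195 ± 42.5 against 5.97 ± 6.69 CPM, a log2 fold change of 5.14 ± 0.44 (adjusted p = 2.51e-10). Next came chromosome 17, 86876889 to 86877168, with 83.4 ± 42.1 against 1.84 ± 1.45 CPM and a log2 fold change of 5.02 ± 0.55 (adjusted p = 1.23e-08). At chromosome 1, 74795996 to 74796207, the means were 5.72 ± 2.15 CPM for Gata4 and 204 ± 49.2 for Mef2c, a log2 fold change of -5.83 ± 0.35 (SE, adjusted p = 4.61e-12). Chromosome 1, 136229684 to 136229886, had 4.2 ± 1.99 against 130 ± 34.8 CPM, a log2 fold change of -5.56 ± 0.40 (adjusted p = 3.14e-11). Next came chromosome 7, 149281126 to 149281350, with 5.78 ± 3.41 against 160 ± 23.8 CPM and a log2 fold change of -5.25 ± 0.37 (adjusted p = 2.68e-11), and Gata4 number 3 lay far below its group there. The other 7 named higher regions lay between 4.14 and 4.81 on the log2 scale and the other 7 lower ones between -4.62 and -5.02, with adjusted p at most 1.27e-08 and 1.01e-09. The regions higher for Gata4 were 46% of the calls, and 60.1% with scaling by library totals.

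Gata4 and Tbx5 with the others differed at 12500 of 25010 regions, the smallest count of the 3 comparisons between factors in these cells. Gata4 was higher at 5855 (median log2 fold change 1.32) and Tbx5 at 6645 (median -1.51). CPM are means ± SD over 5 Gata4 and 4 Tbx5 samples. At chromosome 2, 170186394 to 170186763, the means were 80.5 ± 31.1 CPM for Gata4 and 0.969 ± 1.51 for Tbx5, a log2 fold change of 5.96 ± 0.53 (SE, adjusted p = 3.58e-09). Chromosome 11, 104829799 to 104830074, had 195 ± 42.5 against 5.13 ± 3.74 CPM, a log2 fold change of 5.21 ± 0.33 (adjusted p = 6.21e-11). Next came chromosome 10, 67271994 to 67272270, with 57.5 ± 11.7 against 1.4 ± 1.71 CPM and a log2 fold change of 4.74 ± 0.45 (adjusted p = 5.9e-09). At chromosome 18, 36831937 to 36832140, the means were 2.74 ± 1.21 CPM for Gata4 and 93.9 ± 71.7 for Tbx5, a log2 fold change of -5.17 ± 0.55 (SE, adjusted p = 1.98e-07). Chromosome 18, 75970724 to 75970965, had 5.18 ± 3.98 against 112 ± 87.9 CPM, a log2 fold change of -4.52 ± 0.57 (adjusted p = 3.62e-06). Next came chromosome 16, 92282334 to 92282537, with 5.06 ± 2.35 against 86.4 ± 75.1 CPM and a log2 fold change of -4.32 ± 0.59 (adjusted p = 9.36e-06). Ranks below held 7 more higher regions between 4.02 and 4.63 and 7 more lower ones between -3.62 and -4.26, with adjusted p at most 3.12e-06 and 4.95e-05. Regions higher for Gata4 made up 46.8% of the calls, and 57.7% with scaling by library totals.

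Mef2c and Tbx5 with the others differed at 16431 of 22901 regions. Mef2c was higher at 8403 (median log2 fold change 2.07) and Tbx5 at 8028 (median -1.82). Mean CPM ± SD are over 4 samples of each. At chromosome 12, 86263045 to 86263287, the means were 81.1 ± 22.2 CPM for Mef2c and 2.87 ± 2.14 for Tbx5, a log2 fold change of 5.28 ± 0.53 (SE, adjusted p = 2.03e-07). Chromosome 14, 26303666 to 26303868, had 86.6 ± 10.4 against 2.53 ± 0.736 CPM, a log2 fold change of 5.25 ± 0.39 (adjusted p = 2.29e-08). Next came chromosome 1, 186289312 to 186289514, with 81.6 ± 13.1 against 2.36 ± 1.17 CPM and a log2 fold change of 5.20 ± 0.41 (adjusted p = 3.87e-08). At chromosome 2, 167848939 to 167849277, the means were 4.01 ± 2.59 CPM for Mef2c and 161 ± 101 for Tbx5, a log2 fold change of -5.32 ± 0.50 (SE, adjusted p = 1.25e-07). Chromosome 3, 149092507 to 149092720, had 3.34 ± 3.23 against 83.9 ± 72.1 CPM, a log2 fold change of -4.96 ± 0.72 (adjusted p = 6.13e-06). Next came chromosome 10, 39643052 to 39643532, with 11.7 ± 4.95 against 361 ± 205 CPM and a log2 fold change of -4.89 ± 0.41 (adjusted p = 5.2e-08). Log2 fold changes of the next 7 named higher regions ran from 4.83 to 5.19, and of the next 7 lower ones from -4.44 to -4.84, with adjusted p at most 4.52e-07 and 6.54e-06.

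Profiles of different factors resembled each other more in cells with all 3 factors than alone. The mean Pearson correlation of log2 CPM over regions, between samples of different factors, was 0.322 with all 3 factors and 0.000966 alone for Gata4 and Mef2c, a difference of 0.321. It was 0.558 against 0.165 for Gata4 and Tbx5 (0.393) and 0.366 against 0.00811 for Mef2c and Tbx5 (0.358). Exact two-sided permutation tests over relabellings within each factor gave p = 0.00476, 0.000227 and 0.00245 (adjusted over pairs 0.00476, 0.000681 and 0.00368). They ignore pairing by number, so p may be too small. The p for Gata4 and Tbx5 is the smallest possible, and the measure was chosen after the data had been seen. Within groups the mean correlation was 0.816, 0.856 and 0.882 for Gata4, Mef2c and Tbx5 with the others, and 0.5, 0.937 and 0.823 alone (Gata4 0.841 without number 4).

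**Figure D3:**
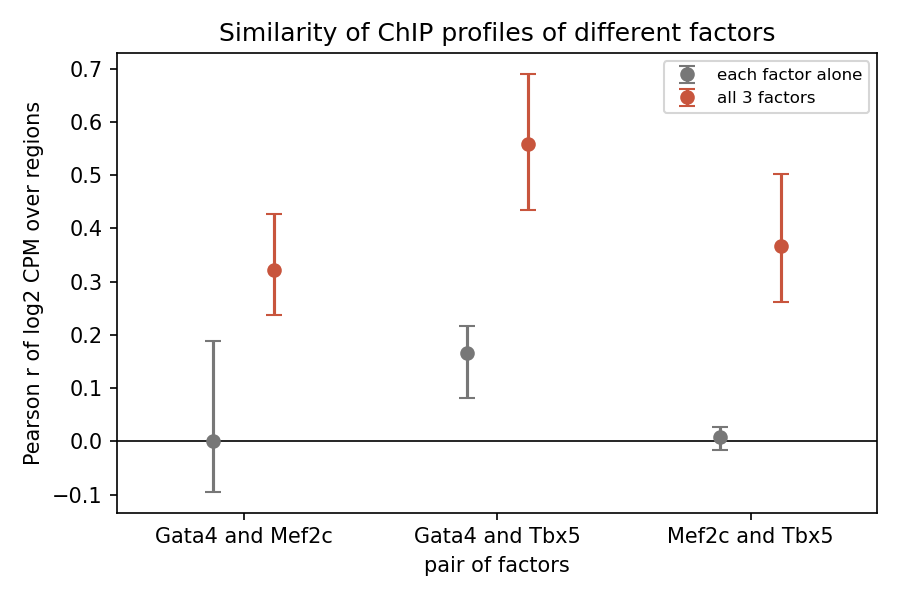
Points are mean Pearson correlations of log2 CPM over regions between samples of different factors, and bars run from the lowest to the highest pair of samples. In each pair of factors the mean with all 3 factors (0.322, 0.558 and 0.366) lies above the mean of the factors alone (0.000966, 0.165 and 0.00811).

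Gata4 reads at the regions of Tbx5 rose when the other factors were present. At the 500 regions most enriched for Tbx5 alone, the log2 share of Gata4 reads relative to 3591 regions enriched for no factor was 0.09 ± 0.27 alone (SD, n = 4) and 1.32 ± 0.33 with the others (SD, n = 5). At the 500 regions most enriched for Mef2c alone it was -0.03 ± 0.40 and 0.68 ± 0.33. The differences were 1.23 (exact permutation p = 0.00794, the smallest for 126 relabellings, adjusted 0.0318) and 0.71 (exact p = 0.0159, adjusted 0.0477). At the regions most enriched for Tbx5 and for Mef2c with the others the differences were 1.73 and 1.18, each with the same smallest exact p and an adjusted p of 0.0318. Without Gata4 alone number 4 the differences were 1.30, 0.82, 1.81 and 1.26, and each exact p was then 0.0179, the smallest for 56 relabellings, with an adjusted p of 0.0537. The reference itself moved, since at the regions enriched for no factor the log2 share over the inputs was -0.34 alone and -0.87 with the others for Gata4, -2.61 and -1.76 for Mef2c and -1.55 and -1.52 for Tbx5. With the share over the inputs and no such reference, the Gata4 differences were 0.70, 0.18, 1.20 and 0.65 in the same order (adjusted exact p = 0.0318, but 0.581 for the second), so a rise at the regions of Mef2c alone depends on the reference. Mef2c and Tbx5 reads at the regions of other factors did not pass the test relative to regions enriched for no factor (adjusted p from 0.274 to 0.971). Over the inputs, Mef2c reads rose by 0.48 and 0.87 at the regions of Gata4 and Tbx5 alone and by 1.05 and 1.58 at those with the others, and Tbx5 reads by 0.38 at those of Gata4 with the others (adjusted exact p = 0.0429 for each). Whether they rose thus depends on the reference too. This comparison was also chosen after the data had been seen.

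At their own strongest regions alone, Mef2c reads stood at a log2 share of 5.90 ± 0.06 alone (SD, n = 3) and 4.08 ± 0.75 with the others (SD, n = 4). The exact permutation test gave p = 0.0286, the smallest for 35 relabellings. Tbx5 reads stood at 4.31 ± 0.15 and 3.42 ± 0.45 at theirs (exact p = 0.0571), and Gata4 reads at 2.08 ± 1.17 and 2.29 ± 0.40 at theirs (exact p = 0.825). Without the library labelled Gata4 alone number 4 the Gata4 values were 2.66 ± 0.27 alone (n = 3) and 2.29 ± 0.40 with the others, a difference of -0.37 (exact permutation p = 0.214 over 56 relabellings). Over the inputs only, with no regions as reference, the values were 3.29 ± 0.03 and 2.32 ± 0.19 for Mef2c (exact p = 0.0286), 2.76 ± 0.13 and 1.90 ± 0.21 for Tbx5 (exact p = 0.0286) and 1.74 ± 1.03 and 1.42 ± 0.23 for Gata4 (exact p = 0.556, or 0.0179 with 2.26 ± 0.14 alone without number 4). These regions were chosen on the libraries of the factors alone, which by itself raises the values alone.

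Each ChIP group was compared with the 6 inputs to find the regions where it was enriched, with changes relative to the median region under TMM scaling. CPM below use library totals, whereas the fold changes use TMM factors, so that the ratio of a pair of means and the fold change can differ. Mef2c alone was higher than input at 9326 of 27784 regions (median log2 fold change 2.57) and lower at 11043. Means and SD of CPM are over 3 Mef2c samples and 6 inputs. At chromosome 3, 88635374 to 88635576, means were 40.1 ± 6.89 CPM in the ChIP and 1.71 ± 4.19 in the input, a count ratio of 68.5 (95% interval 12 to 2730, adjusted p = 1.99e-22). Chromosome X, 38355571 to 38355800, had 252 ± 22.8 against 10.8 ± 6.62 CPM, a log2 fold change of 6.52 ± 0.25 (adjusted p = 7.4e-51). Next came chromosome 1, 14350121 to 14350323, with 344 ± 25 against 16.9 ± 9.92 CPM and a log2 fold change of 6.13 ± 0.21 (adjusted p = 6.85e-55). At chromosome 8, 116332031 to 116332412, means were 1.07 ± 1.06 CPM in the ChIP and 59.7 ± 14.8 in the input, a count ratio of 57.2 (95% interval 19 to 282, adjusted p = 2.21e-11). Chromosome 2, 167162691 to 167163039, had 1.41 ± 1.23 against 67.4 ± 13.6 CPM, a log2 fold change of -3.92 ± 0.52 (adjusted p = 2.38e-11). Next came chromosome 10, 23732835 to 23733081, with 1.39 ± 1.57 against 51.1 ± 29.4 CPM and a log2 fold change of -3.61 ± 0.56 (adjusted p = 8.56e-09). The next 7 gains ranged from 5.62 to 5.93 and the next 7 losses from -3.27 to -3.60, with adjusted p at most 5.72e-40 and 3.04e-08. The total of 20369 was 9736 with the input of the same cells only, 11421 with every library counted separately and 11472 on the mode of the ratio to input. The higher share of calls was 45.8%, but 24% with library totals, 62.7% with the input of the same cells only and 97.6% when samples were scaled on this mode.

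Tbx5 alone was higher than input at 7610 of 22774 regions (median log2 fold change 1.75) and lower at 7924. Means are CPM ± SD over 3 Tbx5 samples and 6 inputs. At chromosome 9, 119378812 to 119379125, the means were 192 ± 59 CPM in the ChIP and 11.5 ± 7.91 in the input, a log2 fold change of 4.30 ± 0.29 (SE, adjusted p = 3.51e-24). Chromosome 15, 103135687 to 103135975, had 483 ± 144 against 35 ± 4.46 CPM, a log2 fold change of 4.25 ± 0.21 (adjusted p = 1.05e-31). Next came chromosome 7, 107739215 to 107739418, with 122 ± 38.4 against 11.9 ± 10.8 CPM and a log2 fold change of 4.22 ± 0.35 (adjusted p = 2.17e-19). At chromosome 8, 108094239 to 108094540, means were 0.785 ± 1.36 CPM in the ChIP and 48.1 ± 21.3 in the input, a count ratio of 69 (95% interval 12.1 to 2750, adjusted p = 2.97e-09). Chromosome 10, 114616753 to 114617180, had 2.57 ± 2.38 CPM in the ChIP and 60.9 ± 18.5 in the input, a count ratio of 26.1 (95% interval 8.71 to 129, adjusted p = 1.74e-09). Next came chromosome 15, 74662638 to 74662970, with 2.84 ± 3.12 against 50.4 ± 12.8 CPM and a log2 fold change of -3.39 ± 0.56 (adjusted p = 1.49e-07). The other 7 named higher regions lay between 4.03 and 4.22 on the log2 scale and the other 7 lower ones between -2.86 and -3.27, with adjusted p at most 1.59e-18 and 9.87e-07. The total of 15534 fell to 8240 without inputs 1 and 3 and to 8003 without inputs 2, 4 and 5 of the cells with all 3 factors. It was 3470 with the matched input, 10055 with every library counted separately and 9068 on the mode. The higher share was 49%, but 31.3% with library totals, 75.4% with the matched input and 97.4% on the mode.

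Gata4 alone was higher than input at 4812 of 20301 regions (median log2 fold change 1.38) and lower at 2607. Values are mean CPM ± SD over 4 Gata4 samples and 6 inputs. At chromosome 13, 41012516 to 41012779, the means were 81.8 ± 24.9 CPM in the ChIP and 11.5 ± 5.36 in the input, a log2 fold change of 2.99 ± 0.41 (SE, adjusted p = 4.28e-05). Chromosome 3, 108689187 to 108689398, had 94 ± 42.3 against 14.2 ± 3.91 CPM, a log2 fold change of 2.87 ± 0.42 (adjusted p = 0.000131), and number 4 lay far below the other Gata4 samples there. Next came chromosome 15, 101154604 to 101155041, with 97.6 ± 45.5 against 17.6 ± 9.52 CPM and a log2 fold change of 2.62 ± 0.42 (adjusted p = 0.000215). At chromosome 6, 31126944 to 31127272, the means were 14.5 ± 17.3 CPM in the ChIP and 68.9 ± 15.7 in the input, a log2 fold change of -2.34 ± 0.45 (SE, adjusted p = 0.000441). Chromosome 2, 168429117 to 168429620, had 13.9 ± 14.8 against 64.6 ± 15.6 CPM, a log2 fold change of -2.28 ± 0.45 (adjusted p = 0.000466). Next came chromosome 17, 85039842 to 85040286, with 14.8 ± 14.1 against 62.7 ± 19 CPM and a log2 fold change of -2.09 ± 0.44 (adjusted p = 0.000787), and number 4 lay far above the other Gata4 samples there. Log2 fold changes of the next 7 named higher regions ran from 2.47 to 2.60, and of the next 7 lower ones from -1.75 to -1.90, with adjusted p at most 0.000274 and 0.00362. With the Gata4 alone input only, edgeR called 0 regions at an adjusted p under 0.05, with 2429 at an unadjusted p under 0.05, while DESeq2 called 6545 against all inputs. None of the 6 regions named with full values kept its call there, with log2 fold changes of 3.78, 3.04, 4.05, -2.61, -2.50 and -2.07 in the order given. Their adjusted p was 0.351 to 0.58 there and at most 0.0157 under every other alternative that gave them a value. The total of 7419 became 17100 without number 4 (8579 higher and 8521 lower), 1712, 1455 or 1768 without number 1, 2 or 3, and 4777 on the mode. It was 1095 or 1143 without inputs 1 and 3 or inputs 2, 4 and 5 of the cells with all 3 factors. Fewer regions were tested for both Gata4 and Mef2c alone without number 1, 2 or 3 or either set of inputs, as given below. The higher share of 64.9% was 41.9% with library totals, 79.1% with DESeq2, 75.1% with no filter, 79.2% in a single fit of all groups, 51.4% with every library counted separately and 98.9% on the mode.

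With the others, Gata4 was higher than input at 6823 of 22925 regions (median log2 fold change 1.02) and lower at 6462. The chromosome 11 region seen in the comparisons between factors was among the strongest over input too. CPM are means ± SD over 5 Gata4 samples and 6 inputs. At chromosome 17, 26782116 to 26782382, the means were 110 ± 12.7 CPM in the ChIP and 14 ± 7.59 in the input, a log2 fold change of 3.11 ± 0.31 (SE, adjusted p = 1.1e-11). Chromosome 5, 140280185 to 140280443, had 180 ± 23.3 against 21.5 ± 11.1 CPM, a log2 fold change of 3.07 ± 0.28 (adjusted p = 5.38e-13). Next came chromosome 11, 104829799 to 104830074, with 195 ± 42.5 against 27.7 ± 9.61 CPM and a log2 fold change of 3.0 ± 0.26 (adjusted p = 3.63e-13). At chromosome 3, 69363485 to 69363958, the means were 17.7 ± 9.74 CPM in the ChIP and 70.8 ± 27.4 in the input, a log2 fold change of -2.08 ± 0.31 (SE, adjusted p = 3.41e-07). Chromosome 8, 36430185 to 36430545, had 17.3 ± 8.37 against 67 ± 17.5 CPM, a log2 fold change of -1.95 ± 0.31 (adjusted p = 9.74e-07). Next came chromosome 2, 19529377 to 19529803, with 14.7 ± 10.9 against 61.9 ± 22.6 CPM and a log2 fold change of -1.91 ± 0.33 (adjusted p = 7.55e-06). Ranks below held 7 more higher regions between 2.69 and 2.87 and 7 more lower ones between -1.67 and -1.85, with adjusted p at most 3.6e-09 and 4.13e-05. The total of 13285 was 7803 without inputs 1 and 3 and 5368 without inputs 2, 4 and 5 of these cells. It was 6261 with every library counted separately, 8526 beyond a log2 fold change of 1, 2646 on the mode and 5027 with replicate numbers as a block. The higher share of 51.4% was 35% with library totals, 63% in a single fit and 82.8% on the mode.

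Mef2c with the others was higher than input at 8885 of 23283 regions (median log2 fold change 1.66) and lower at 8274. Mean CPM ± SD are over 4 Mef2c samples and 6 inputs. At chromosome 7, 56103423 to 56103625, the means were 162 ± 22.5 CPM in the ChIP and 9.97 ± 1.71 in the input, a log2 fold change of 4.53 ± 0.30 (SE, adjusted p = 2.11e-14). Chromosome 4, 135232467 to 135232675, had 283 ± 133 against 19.2 ± 7.66 CPM, a log2 fold change of 4.38 ± 0.29 (adjusted p = 1.99e-14). Next came chromosome X, 7492807 to 7493009, with 50.9 ± 7.39 against 3.98 ± 4.02 CPM and a log2 fold change of 4.19 ± 0.45 (adjusted p = 6.64e-10). At chromosome 2, 77757143 to 77757404, the means were 27.5 ± 20 CPM in the ChIP and 355 ± 252 in the input, a log2 fold change of -3.16 ± 0.85 (SE, adjusted p = 0.00872). Chromosome 2, 27441284 to 27442083, had 8.96 ± 5.48 against 88.9 ± 32.7 CPM, a log2 fold change of -2.75 ± 0.41 (adjusted p = 4.42e-07). Next came chromosome 13, 60056038 to 60056938, with 8.71 ± 2.72 against 91.6 ± 20 CPM and a log2 fold change of -2.75 ± 0.35 (adjusted p = 1.99e-08), and Mef2c number 4 lay far below its group there. The next 7 gains ranged from 4.07 to 4.18 and the next 7 losses from -2.34 to -2.72, with adjusted p at most 7.4e-11 and 7.88e-06. The total of 17159 was 11361 without inputs 2, 4 and 5 of these cells, 9105 with every library counted separately and 9104 with replicate numbers as a block. The higher share of 51.8% was 31.4% with library totals and 98% on the mode.

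Tbx5 with the others was higher than input at 9578 of 27074 regions (median log2 fold change 1.54) and lower at 10018. Means and SD of CPM are over 4 Tbx5 samples and 6 inputs. At chromosome X, 96372095 to 96372391, the means were 246 ± 162 CPM in the ChIP and 14.5 ± 12.4 in the input, a log2 fold change of 4.65 ± 0.48 (SE, adjusted p = 3.45e-07). Chromosome X, 20527791 to 20527994, had 49.3 ± 6.84 against 3.12 ± 3.2 CPM, a log2 fold change of 4.49 ± 0.47 (adjusted p = 2.21e-11). Next came chromosome 16, 92282334 to 92282537, with 86.4 ± 75.1 against 9.64 ± 7.63 CPM and a log2 fold change of 3.96 ± 0.70 (adjusted p = 0.000157). At chromosome 10, 65440870 to 65441469, the means were 7.87 ± 3.28 CPM in the ChIP and 75.5 ± 35.9 in the input, a log2 fold change of -2.59 ± 0.38 (SE, adjusted p = 8.22e-08). Chromosome 7, 38963784 to 38963984, had 15.9 ± 10.1 against 137 ± 76.7 CPM, a log2 fold change of -2.51 ± 0.34 (adjusted p = 3.9e-08). Next came chromosome 6, 143365162 to 143365687, with 7.93 ± 4.2 against 61.9 ± 19 CPM and a log2 fold change of -2.46 ± 0.37 (adjusted p = 1.95e-07). Log2 fold changes of the next 7 named higher regions ran from 3.52 to 3.92, and of the next 7 lower ones from -2.38 to -2.44, with adjusted p at most 4.32e-10 and 8.2e-07. The total of 19596 was 8601 with every library counted separately. The higher share of 48.9% was 33.5% with library totals and 99.1% on the mode.

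Regions enriched over input for more than 1 factor were counted. With all 3 factors, Gata4 and Tbx5 shared 3673 of 6324 and 8209 enriched regions, 58.1% of the smaller list, against 2349 for independent lists (odds ratio 3.43, 95% interval 3.23 to 3.65, adjusted p = 6e-300). Alone they shared 996 of 3592 and 5191, against 1004 (odds ratio 0.987, adjusted p = 0.787). Alone, Gata4 and Mef2c shared fewer than independent lists, 845 against 1327 (odds ratio 0.477, 95% interval 0.438 to 0.518, adjusted p = 3.94e-76), as did Mef2c and Tbx5, 1404 against 2074 (odds ratio 0.484, adjusted p = 2.93e-104). With all 3 factors these pairs shared 1861 against 1853 (odds ratio 1.01, adjusted p = 0.787) and 2728 against 2601 (odds ratio 1.12, 95% interval 1.05 to 1.19, adjusted p = 0.000245). All tests were Fisher's exact tests. Part of an excess may come from the shared inputs. With the inputs split between the factors the odds ratio with all 3 factors was 2.02 for Gata4 and Tbx5 (exact p = 4.21e-96), 0.601 for Mef2c and Tbx5 (exact p = 8.3e-54) and 0.765 for Gata4 and Mef2c (exact p = 4.62e-12), so that the last pairs then shared fewer regions than independent lists. Alone it was 0.351 for Gata4 and Tbx5 (exact p = 1.32e-10), 0.369 for Gata4 and Mef2c and 0.281 for Mef2c and Tbx5.

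The shared counts depended on single samples more than the odds ratios did. Without Gata4 alone number 4, Gata4 alone shared 1611 regions with Mef2c against 2368 for independent lists, and 1950 with Tbx5 against 1968. Without Gata4 alone number 1, 2 or 3 it shared 237, 199 or 219 with Mef2c and 242, 208 or 205 with Tbx5. Without inputs 1 and 3 of the cells with all 3 factors, Gata4 and Mef2c, Gata4 and Tbx5, and Mef2c and Tbx5 shared 105, 32 and 502 regions alone and 791, 2144 and 1627 with all 3 factors, and without inputs 2, 4 and 5 these were 65, 37 and 295 and 602, 1387 and 1209. The odds ratio of Gata4 and Mef2c alone was 0.777 or 0.716 without these inputs in turn, still below 1 and past the test. Others changed side of the test when a sample was left out. That of Gata4 and Tbx5 alone passed the test below 1 when any 1 sample or input was left out (0.556 to 0.892), except Gata4 alone number 4 (0.982) and the input of Tbx5 alone (1.03). That of Gata4 and Mef2c with all 3 factors rose past the test without Gata4 numbers 1 and 6, 2, 3 or 5 (1.14 to 1.21) and without inputs 2, 4 and 5 (1.37). It fell below 1 (0.906 to 0.981) without Gata4 number 4, input 6, Mef2c number 3 or 5, the input of Gata4 alone or the input of Mef2c alone. That of Mef2c and Tbx5 with all 3 factors fell below 1 (0.864 to 0.993) without inputs 1 and 3, inputs 2, 4 and 5, input 6, Tbx5 number 4 or the input of Mef2c alone, and was 1.02 without the input of Gata4 alone.

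Regions that gained a factor with the others were wider than those that lost it. Regions wider than 322 bp made up 48.1% of Gata4 gains and 22.9% of its losses (odds ratio 3.13, adjusted p = 2.37e-102, Fisher's exact test), or an odds ratio of 1.97 without Gata4 alone number 4. They made up 41.1% and 21.2% for Mef2c (odds ratio 2.59, adjusted p = 7.15e-119) and 46% and 35.9% for Tbx5 (odds ratio 1.52, adjusted p = 4.24e-14).

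Gains and losses were also uneven over chromosomes. The share of gains among the calls of a chromosome differed from that of the other chromosomes on 11 chromosomes for Mef2c, 10 for Tbx5 and 2 for Gata4 (Fisher's exact test, adjusted p under 0.05). For Mef2c, gains were 39.1% of the calls on chromosome 13 (adjusted p = 1.45e-09), 62% on chromosome 11 (adjusted p = 2.58e-07) and 61.5% on chromosome 8 (adjusted p = 2.95e-05). For Tbx5 they were 68.1% on chromosome 11 and 39.2% on chromosome 13. For Gata4 they were 43.2% on chromosome 10 (adjusted p = 0.00478) and 61.6% on chromosome 7 (adjusted p = 0.016). Shares of input counts per chromosome differed as well, with a log2 share higher with all 3 factors by 0.25 on chromosomes 8 and 15, and log2 differences of -0.22 on chromosome 12, -0.20 on chromosome 13 and -0.19 on chromosome X.

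**Figure D4:**
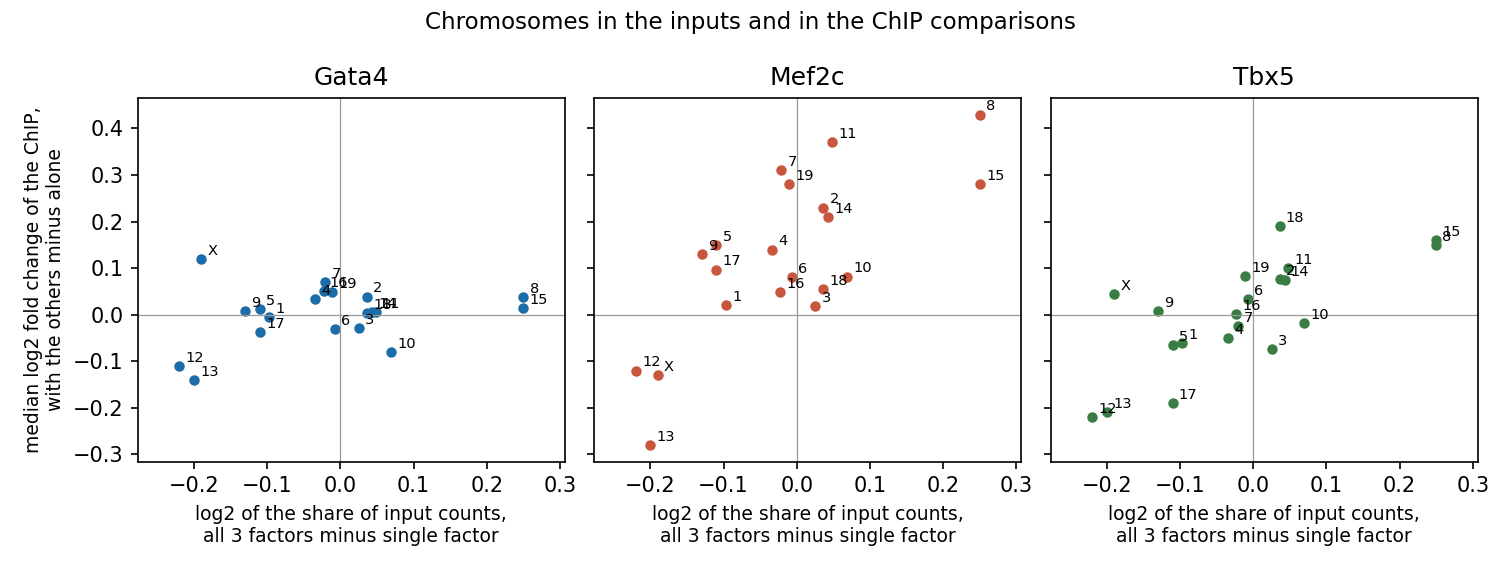
Each point is a chromosome. The horizontal axis gives the log2 share of input counts with all 3 factors minus that with a single factor, and the vertical axis the median log2 fold change of the ChIP from alone to with the others, with chromosomes 8 and 15 farthest to the right at 0.25.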

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

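The tests of enrichment and chromosome shares for the library labelled Gata4 alone number 4 were chosen after the result was seen. Values were tested within groups of 4 to 10 samples for a sample far from the rest, by its gap to the nearest sample as a share of the group's range. In 117 groups of values tested, 11 had such a sample, 2 of 25 library measures and 9 of 92 region values, while chance gives about 1 in 20 groups.

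The library labelled Gata4 alone number 4 accounted for 6 of the 9 region values. On chromosome 11, 104829799 to 104830074, its log2 CPM was 3.55 against 7.61 to 8.41 in the other Gata4 alone samples (gap 0.834 of the range). At chromosome X, 38986010 to 38986343, it was 4.02 against 2.61 to 2.84 (0.842), and at chromosome 5, 5610421 to 5610643, it was 4.65 against 6.52 to 6.86 (0.846). Chromosome 3, 69024560 to 69024785, had 4.37 against 6.73 to 6.79 (0.973) and chromosome 3, 108689187 to 108689398, had 5.09 against 6.76 to 6.96 (0.89). At chromosome 17, 85039842 to 85040286, it was 5.27 against 3.22 to 3.49 (0.872).

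This library had a log2 enrichment of 0.13 at the regions most enriched for Gata4 with the others, against 1.51 to 1.69 in the other Gata4 alone samples. Depth is excluded as the reason, because the other 3 libraries thinned to its total kept at least 1.5. A weak pulldown from the cells that gave the Gata4 alone input is argued against too, since its chromosome shares lay 0.142 from that input (root mean square of log2 shares), and the other single-factor inputs lay at most 0.0774 from it. It lay 0.0343 from the mean of the inputs with all 3 factors, within the 0.0657 that those inputs reach, so it may be an unenriched library of that cell population, through its label or a failed pulldown. No biological explanation was tested, and nothing in the tables tells a wrong label from a failed pulldown.

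In cells with all 3 factors, Mef2c number 3 had 11.7 CPM on chromosome Y against 0 to 1.74 in the other Mef2c samples (gap 0.851 of the range), and Tbx5 number 3 had 11.7 against 0 to 1.72 (0.853). Gata4 numbers 1, 3 and 6 of these cells had 194, 138 and 209 CPM there, number 4 had 25.6, and numbers 2 and 5 had 3.59 and 1.06. Inputs 1, 3 and 6 had 37.5, 43.1 and 42.3, input 4 had 10.3, and inputs 2 and 5 had 0. Alone, inputs had 30.8 to 71.9 CPM (3 to 9 counts each), Gata4 18 to 284, Mef2c 5.31 to 8.71 and Tbx5 11.9 to 18.8. Numbers 2 and 5 with all 3 factors lay below these in every ChIP and input, so cell populations differed in part.

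Mef2c with the others number 4 had a log2 CPM of 5.17 against 6.43 to 6.49 at chromosome 7, 136955287 to 136955503 (0.956), and of 2.89 against 3.63 to 3.72 at chromosome 13, 60056038 to 60056938 (0.896). Gata4 with the others number 3 had 1.45 against 3.12 to 3.49 at chromosome 7, 149281126 to 149281350 (0.82).

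A difference of the change from alone to with the others was found between factors by the test of that difference itself, at 4142 regions for Gata4 and Mef2c, 1100 for Gata4 and Tbx5 and 4070 for Mef2c and Tbx5. Of 100 regroupings, 2 gave as many regions for Gata4 and Mef2c (the real one among them, with a highest other of 5121), 1 for Gata4 and Tbx5 (highest other 11) and 1 for Mef2c and Tbx5 (highest other 1363). Another 100 regroupings, added later, kept same-numbered samples of the cells with all 3 factors together. Only the real one then gave as many (highest others 254, 1 and 0). The first set was raised from 40 to 100 after 40 had given 2, 1 and 1. Chance thus stays open for Gata4 and Mef2c and is argued against for the other pairs. The highest other for Gata4 and Mef2c exceeded the real count and points to a structure of the samples.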

How the results depend on the processing

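Alternatives chosen after the data were examined were the count of every library separately, the libraries with all 3 factors by number, scaling on the mode of the ratio to input, the block with the inputs of the same cells, split inputs, and, for the differences of context effects, their overlap and co-occupancy, the omission of samples and of the filter, and paired regroupings. So were those of profile similarity, reads in other factors' regions and width. Alternatives for gene lists and motifs were not run. Of the 1420 values of the 90 regions named with full values, 1414 kept their direction and side of the test and 6 kept only their direction, those of Gata4 alone with the matched input. A region left out by the filter under an alternative has no value there. Among the main results, 163 values outside the omission of a sample were within these limits, 17 counts or ratios moved, 11 passed the test newly, 1 lost it and 7 reversed. The cause was not tested unless it is given. Depth limits the inputs most, at 97474 counts for the shallowest.

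The 6589 calls for Gata4 between alone and with the others were 2864 with libraries 1, 3 and 6 and 3848 with 2, 4 and 5, where fewer samples entered. Without Gata4 alone number 4 these were 8825 and 9357. Against the matched input only, where the input arm holds 1 library, Gata4 alone had 0 calls with edgeR (2429 at an unadjusted p under 0.05, and 6545 with DESeq2 against all inputs), Mef2c alone 9736 and Tbx5 alone 3470. Scaled on the mode, these counts were 4777, 11472 and 9068, and Gata4 with the others had 2646. With every library counted separately Mef2c and Tbx5 alone had 11421 and 10055 calls against input, and Gata4, Mef2c and Tbx5 with the others 6261, 9105 and 8601. Gata4 with the others had 8526 beyond a log2 fold change of 1, where a criterion was added.

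The co-occupancy odds ratio of Gata4 and Tbx5 alone was 0.877 with a log2 fold change over 1, 0.811 with no filter, 0.351 with the inputs split between the factors and 0.757 with every library counted separately. That of Gata4 and Mef2c with all 3 factors was 1.17, 0.901, 0.765 and 1.47 in this order. That of Mef2c and Tbx5 with all 3 factors was 0.832 with a log2 fold change over 1 and 0.601 with split inputs. Split inputs also moved the other odds ratios, as given above.

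With the replicate number as a block, the paired comparisons of Gata4 and Mef2c against Tbx5 with all 3 factors had 14642 and 18215 calls, and the block moved no count between ChIP groups by over 1.5 times. Numbers that do not pair samples gave 4641, 10215 and 4864 calls between alone and with the others for Gata4, Mef2c and Tbx5 (4961, 10486 and 5624 in the same samples without the block), and 18472, 14082 and 16820 for the factors alone. Gata4 and Mef2c with all 3 factors, paired through Tbx5, gave 17128. With the inputs of the same cells the block gave 5027, 9104 and 13395 for Gata4, Mef2c and Tbx5 with the others. Every sample correlated best with its own number only for Mef2c and Tbx5 with all 3 factors.

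Over the inputs, without the regions enriched for no factor as reference, the difference of Gata4 reads at the regions of Mef2c alone fell to 0.181 and no longer passed the test. Those of Mef2c reads at the regions of Gata4 alone and of Tbx5 reads there turned from -0.361 and -0.00597 to 0.48 and 0.0161, and that of Gata4 reads at the same regions to -0.317. Mef2c reads passed the test newly at 0.867 for Tbx5 alone, and 1.05 and 1.58 for Gata4 and Tbx5 with the others, as did Tbx5 reads at -0.866 for Tbx5 alone and 0.379 for Gata4 with the others.

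Leaving out each sample gave 3680 to 11045 calls for Gata4 between alone and with the others, 9732 to 12020 for Mef2c and 3835 to 6646 for Tbx5. Against input the ranges were 1095 to 17100, 14149 to 20882 and 8003 to 15800 for Gata4, Mef2c and Tbx5 alone, and 5368 to 16627, 11361 to 20371 and 14377 to 20509 with the others. Differences between context effects ran from 2555 to 6552 for Gata4 and Mef2c, 494 to 2966 for Gata4 and Tbx5 and 2446 to 4701 for Mef2c and Tbx5. Between factors the ranges were 15932 to 18575, 9543 to 14132 and 16076 to 18521 alone and 15579 to 18128, 11454 to 12659 and 15350 to 16985 with all 3 factors. Co-occupancy odds ratios ran from 0.556 to 1.03 for Gata4 and Tbx5 alone, and from 0.906 to 1.37 for Gata4 and Mef2c and 0.864 to 1.21 for Mef2c and Tbx5 with all 3 factors. The odds ratio of losses shared by Mef2c and Tbx5 ran from 1.05 to 2.31.

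Scaling by library totals moved the median log2 fold change of all tested regions from 0.15 to 0.47 for Mef2c between alone and with the others. For Gata4 and Mef2c, Gata4 and Tbx5, and Mef2c and Tbx5 it went from 0.63, 0.26 and -0.077 to 1.6, 0.46 and -0.84 alone and from 0.082, 0.096 and -0.064 to 0.66, 0.33 and -0.28 with all 3 factors. Against input it went from -0.047, -0.43 and -0.31 to -0.38, -1.9 and -0.98 for Gata4, Mef2c and Tbx5 alone (1.3, 3 and 2.3 on the mode), and from 0.069, -0.11 and -0.079 to -0.2, -0.89 and -0.68 with the others. DESeq2 gave -0.23, -0.37 and -0.32 for these last, 0.41 for Gata4 and Mef2c alone, and the mode 1.6 and 2.1 for Mef2c and Tbx5 with the others.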

Other observations

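Tests chosen only after the result was seen were the regroupings of samples, the classes by partner, the matched odds ratios and the slopes over chromosomes, while the tests of profile similarity against depth, inputs and shared numbers and those of wide regions were written before their values were seen.

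Where Tbx5 alone was enriched and Mef2c alone was not, Gata4 was rarely lost. Of 4479 such regions, 953 gained Gata4 (21.3%) and 50 lost it (1.12%), against 1834 (16.2%) and 2798 (24.7%) of 11312 regions enriched for neither partner. Gains were 95 against 39.6% of calls, an odds ratio of 29.1 (Fisher's exact test, adjusted p = 2.56e-260), or 14.2 (1502 gains, 151 losses) without Gata4 alone number 4. This rests mostly on losses, and regions enriched for neither held more Gata4 alone (mean log2 CPM 5.17 against 4.91). At regions enriched for Mef2c alone only, Gata4 had 518 gains and 297 losses (63.6% gains). Gains were less frequent there (12.4 against 16.2% of regions, odds ratio 0.734, adjusted p = 5.86e-09), and losses were 7.13 against 24.7%. Without number 4 the calls were 1148 and 517 (68.9%), against 3076 and 4386 (41.2%) for neither, and 26.5 against 26.1% of regions gained Gata4 (odds ratio 1.02, adjusted p = 0.837). Mef2c had 1523 gains and 254 losses at 4202 regions enriched for Tbx5 alone only, 85.7% against 44.1% for neither (odds ratio 7.59, adjusted p = 3.2e-246). Of these regions 6.04% lost Mef2c against 39.4%, while 36.2% gained it against 31.1%, but 20.5 against 20.8% with DESeq2 and 20.9 against 23.8% with libraries 1, 3 and 6 with all 3 factors. Tbx5 calls at regions enriched for Gata4 alone only were 53% gains, against 53.8% for neither (odds ratio 0.968, adjusted p = 0.776). Gains (9.14 against 21.2% of regions, odds ratio 0.375, adjusted p = 4.57e-39) and losses (8.12 against 18.2%) were rarer there. At regions of Mef2c alone only, Tbx5 calls were 66.3% gains (odds ratio 1.69, adjusted p = 1.09e-12), but 57.1 against 58.2% with libraries 1, 3 and 6 (odds ratio 0.957, adjusted p = 0.665). Gains were rarer there (18.8 against 21.2% of regions, odds ratio 0.862, adjusted p = 0.0035), and so were losses (9.55 against 18.2%).

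A hypothesis drawn from these shares was that Gata4 and Mef2c gain more often at regions Tbx5 can hold alone. For Mef2c it was not borne out once regions were matched on the level of the factor alone (odds ratio of a gain 0.519, 95% interval 0.471 to 0.571) or on that level and width (0.388, 0.35 to 0.429). For Gata4 it stays open, since the odds ratio was 1.1 matched on level (95% interval 1.01 to 1.21) and 0.721 matched on level and width (0.653 to 0.795). Without Gata4 alone number 4 these were 0.915 (0.835 to 1) and 0.545 (upper bound 0.601).

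Profiles were more alike with all 3 factors than alone, by 0.321, 0.393 and 0.358 in mean correlation. Lowest differences of 0.282 with ChIPs thinned to 222761 counts and 0.311 between samples of different numbers argue against unequal depth and shared numbers. Regressing out the inputs left at least 0.259. Inputs are noisy (r 0.121 to 0.252 between them alone, 0.447 to 0.647 with all 3 factors), so a shared input profile stays open. Cell populations differed in part in Y reads and are confounded with the factors present. Such a difference and antibody cross-reaction in cells with every factor were not tested and stay open beside shared occupancy.

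Calls of the context comparisons leaned one way on some chromosomes, and the number of chromosome copies in the cell populations may contribute. Over 20 chromosomes the median log2 fold change followed the log2 difference of the inputs with a slope of 1.04 for Mef2c (95% interval 0.575 to 1.5, Pearson r 0.743, permutation p = 0.00018, Spearman rho 0.606 with permutation p = 0.0054, r 0.678 without the 2 farthest chromosomes) and 0.685 for Tbx5 (0.374 to 0.997, r 0.736, permutation p = 2e-04, rho 0.71 with p = 0.00058, r 0.665). Adjusted over the 6 relations computed, both gave 6e-04. For Gata4 the slope was 0.123 (-0.11 to 0.357, r 0.253, permutation p = 0.279, adjusted 0.335, rho 0.125) but 0.492 (0.257 to 0.726, r 0.72) without the library labelled number 4. The cause of that change was not tested, and a slope of 0 and an effect of copy number cannot be told apart for Gata4. Wider regions on these chromosomes are argued against by correlations with the share of wide regions of -0.228, -0.229 and -0.559 for Gata4, Mef2c and Tbx5, which are below 0.

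Other splits of the same samples were tried for every count of calls between groups. Alone against with the others, 1 of 100 splits (the real one) called as many regions for Gata4 (6589, highest other 2369), and 1 of 35 for Mef2c (11648, 3372) and Tbx5 (5524, 3228). For the factors alone, 1 of 35 did so for Gata4 and Mef2c (17871, highest other 15640) and for Gata4 and Tbx5 (13397, 12637). In both, the highest other moved Gata4 alone number 4 to the samples of the other factor. For Mef2c and Tbx5 alone (16956, highest other 0) the 10 splits are too few for a share under 0.05. With all 3 factors the numbers were 1 of 100 for Gata4 and Mef2c (16513, highest other 12363) and for Gata4 and Tbx5 (12500, 8900), and 1 of 35 for Mef2c and Tbx5 (16431, 0). Against input they were 3 of 100 for Gata4 alone (7419, highest other 12720), 1 of 84 for Mef2c alone (20369, highest other 1) and 1 of 84 for Tbx5 alone (15534, highest other 0). With the others they were 1 of 100 each for Gata4 (13285, highest other 10239), Mef2c (17159, 9027) and Tbx5 (19596, 13671). Replicate numbers pair the samples of Gata4 or Mef2c with those of Tbx5 in cells with all 3 factors. Splits that part all 4 pairs number 16 and 8, too few for a share under 0.05 (highest others 4189 and 0). Gata4 and Mef2c there, paired through Tbx5 (same-numbered r 0.079 to 0.36), were not split by pairs. Chance stays open for these 3 counts, for Mef2c and Tbx5 alone and for Gata4 alone against input. The split of the last that called 12720 exchanged number 4 with the input of Tbx5 alone, which points to a structure of the samples. For the others, taken singly with no correction, chance is argued against, and 1 of 35 is the smallest share possible.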
